A study of Mus musculus with 8 samples.

How the data were processed

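RNA was measured by SMART-Seq2 sequencing, a method that amplifies full-length cDNA from few cells, in 8 libraries of sorted mouse liver mesenchymal cells. Per the labels' protocols, livers were perfused and digested with pronase and collagenase, non-parenchymal cells were enriched on a gradient, and cells were sorted straight into a buffer for RNA extraction. Per the labels, all mice were 8 weeks old, of a mixed C57BL/6 and SWR/J background, and carried an inducible Cre driven by Gli1 with an Ai9 reporter. The labels do not state how the stellate cells were recognised in the sort, nor whether the libraries of a group came from separate animals.

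Per the submitters' processing notes, reads were checked with FastQC, aligned to the mm10 genome with STAR 2.5.2b, counted per gene with featureCounts and analysed with DESeq2. The annotation release and the other versions are not given in the sources used here. The deposited values are CPM, reads of a gene scaled to a library total of 1000000, in 1 table of 30395 genes by 8 libraries. Multiplying each deposited CPM column by 1 factor made 100.0% of its values whole within 0.01 read, so the reads assigned to genes could be recovered. These totals ran from 11261775 to 19180370 reads, and 1 read stood for 0.0521 to 0.0888 CPM. Gene identifiers were matched to the GENCODE M21 annotation of mm10, which held 30233 of them (99.47%) and lacked 162. The identifier versions were the same for 80.0%. Symbols and coordinates come from that annotation. Counting without regard to strand cannot tell a gene from an antisense or overlapping gene, and reads shared by near-identical family members such as Mup20 and Serpina3n are uncertain.

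The libraries were grouped by cell type and by injury, 2 in each of 4 groups. The main comparisons were Gli1 cells against stellate cells in the uninjured liver, the same comparison after ligation, ligated against uninjured Gli1 cells, ligated against uninjured stellate cells, and the difference between the last 2 (Gli1 minus stellate), which is called the interaction. No pair of ligation comparisons shares a library. The planned main test was edgeR. Although reads were recovered, limma 3.58.1 with a mean-variance trend and robust empirical Bayes moderation was used on log2(CPM + 1) under R 4.3.3. It was 1 fit of all 4 groups with 4 residual degrees of freedom. The filterByExpr rule of edgeR 4.0.16 with a minimum count of 10 kept 17461 genes and removed 12934. P-values are 2-sided and Benjamini-Hochberg adjusted within a comparison, and an adjusted p below 0.05 was called. Differences are log2 differences ± standard error (SE) from limma unless another tool is named, and levels are mean CPM ± standard deviation (SD) over 2 libraries. The added 1 CPM pulls differences of low genes towards 0. Where 1 group had no read, a floor of 3 reads per library was used for the smallest ratio. Where it had 1 to 3 reads, the ratio is given with its 95% counting interval. Floors and intervals cover counting error only, since amplified reads are not independent molecules.

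Before the data were examined, 29 gene lists with 433 genes were fixed: hepatic stellate cell markers, portal fibroblast markers, Hedgehog pathway, retinoid handling, contractile genes, fibrillar collagens and collagen processing, myofibroblast secreted genes, elastic fibre genes, basement membrane genes, TGF-beta ligands, receptors and targets, PDGF pathway, cell cycle genes, cytokines and chemokines, complement genes, interferon response, Wnt and R-spondin genes, epithelial niche ligands, unfolded protein response, cholesterol synthesis, immediate early genes, and markers of hepatocytes, cholangiocytes, endothelium, macrophages, lymphocytes and neutrophils, mesothelium, smooth muscle and pericytes, Schwann cells and erythroid cells. Of these, 28 had at least 3 tested members. Each was tested with limma's camera against all other genes on log2(CPM + 1), in place of the edgeR scale planned, with a preset correlation of 0.01 and, as an alternative, with a correlation estimated from the residuals. Named genes followed a rule of the same date. It takes, in each comparison, the 8 largest differences in each direction among called genes that have at least 10 CPM in the higher group and no overlap between the libraries of the groups, without genes known only as predicted models. It adds up to 4 members of each list with the smallest p, and Gli1, Lrat, Reln, Des, Thy1, Cd34, Acta2, Col1a1, Timp1, Pdgfrb, Pdgfra and Mki67 always. For the interaction, and for a comparison without a called gene, it takes the 5 smallest p in each direction. Genes beyond that rule belong to the fixed lists, or are said to be chosen after the values were seen.

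Alternatives planned with the design were DESeq2 1.42.0 on recovered reads, limma-voom with sample quality weights on these reads with TMM factors, RLE scaling, no filter, a filter at a mean of 50 reads (12713 genes), the replicate number as a block over all libraries and within injury state, a fit of only the 2 groups compared, and leaving out each library. Alternatives chosen after seeing the data were limma-voom without the weights, an edgeR quasi-likelihood fit, TMM scaling, added values of 0.25 and 4 CPM, and leaving out together the 2 libraries with the most RNA of other cells. These made 22 settings. Correlations between libraries and principal components used log2(CPM + 1). Overlaps of called genes were tested with Fisher's exact test among the genes tested. The scripts used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

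The fits were tested on simulated data with 200 changed genes of 2-, 4- and 16-fold, modelled on means and spread over all groups. In the design of the uninjured cell types limma recovered 29.4% of 16-fold, 6.6% of 4-fold and 0% of 2-fold changes, and 16.7% of its calls were false. For the ligated cell types the recovery was 36.4%, 4.3% and 0% with 15.6% false, for ligation in Gli1 cells 25.7%, 2.6% and 2% with 18.5% false, and for ligation in stellate cells 27.4%, 7.1% and 0% with 15.4% false. False calls made up 14.7%, 3.4%, 9.5% and 5.3% of edgeR calls in the same order, and 72.5%, 69.2%, 69.6% and 70.9% of DESeq2 calls. Camera found the changed list in all 4 designs (adjusted p = 4.47e-15, 8.83e-08, 1.3e-12 and 9.71e-16) and called 0 of 20 random lists. Lists of correlated genes were not simulated. With 2 libraries in a group a permutation of labels cannot reach a small p, so all tests rest on spread shared across genes and groups.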

Results

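RNA was measured in Gli1+ peribiliary mesenchymal cells, called Gli1 cells here, which lie around the bile ducts and carried a reporter under the Hedgehog target gene Gli1, and in hepatic stellate cells, the vitamin A storing pericytes of the sinusoids. Both came from uninjured livers and from livers 5 days after bile duct ligation, an operation that blocks bile flow, with 2 libraries in each of the 4 groups. Reads assigned to genes numbered 11261775 and 17526202 in uninjured Gli1 libraries 1 and 2, 16351324 and 19180370 in uninjured stellate libraries, 12406792 and 16704166 in ligated Gli1 libraries, and 17129100 and 11771666 in ligated stellate libraries. Genes with at least 1 read numbered 18319 and 19300 in uninjured Gli1 cells, 16249 and 15963 in uninjured stellate cells, 21239 and 22897 in ligated Gli1 cells, and 19844 and 18919 in ligated stellate cells. Correlations across genes between the libraries of a group were 0.867 for uninjured Gli1 cells, 0.842 for uninjured stellate cells, 0.916 for ligated Gli1 cells and 0.936 for ligated stellate cells, where genes are not independent replicates. The first principal component held 47.3% of the variance and separated the cell types, and the next held 15% and separated ligated from uninjured libraries. All p-values measure only the spread between these samples, since the labels do not say that the libraries are separate animals. The median of all genes was 0.30 above 0 for Gli1 against stellate cells in the uninjured liver and 0.23 after ligation (0.13 and 0.09 with TMM scaling), 0.12 for ligation in Gli1 cells, 0.18 for ligation in stellate cells and −0.11 for the interaction. Medians of gene lists are given relative to it, and in no list that passed did this median, the mean and camera's direction differ in sign.

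The first comparison asked how Gli1 cells differ from stellate cells in the uninjured liver. Gli1 cells had far more RNA of portal fibroblast genes and stellate cells far more of stellate cell markers. Dpt, a matrix protein of adventitial fibroblasts, averaged 1608 ± 588 CPM (SD, n = 2) in Gli1 cells and 1.23 ± 0.698 CPM in stellate cells, a log2 difference of 9.48 ± 0.43 (adjusted p = 9.36e-05). Lrat, which esterifies retinol for storage, averaged 24.8 ± 15.6 CPM in Gli1 cells and 2308 ± 673 CPM in stellate cells (−6.60 ± 0.61, adjusted p = 0.000725). Gli1 itself, which drove the reporter of the sort, averaged 11.2 ± 5.18 CPM in Gli1 cells with no read in stellate cells, at least 66.2-fold (3.55 ± 0.72, adjusted p = 0.0175; 0.0563 with edgeR and up to 0.0595 with a library left out).

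Of 17461 genes tested, 1771 differed, 1289 higher and 482 lower in Gli1 cells, against 1190 called with edgeR. The largest differences upward were C3, the central complement protein, at 10.83 ± 0.61, the growth factor binding protein Igfbp6 at 10.45 ± 0.41, the protease inhibitor Slpi at 10.41 ± 1.07 and the mucosal glycoprotein Dmbt1 at 10.02 ± 0.74. Next came Igfbp5, also a growth factor binding protein, at 9.96 ± 0.80, the membrane glycoprotein Gpm6a at 9.78 ± 0.73, the keratin Krt19 at 9.57 ± 0.53 and mesothelin, Msln, at 9.56 ± 0.58. The largest adjusted p among these was 0.00108. C3 averaged 14610 ± 12130 CPM against 5.49 ± 0.416, and Igfbp6 2633 ± 37.0 CPM against 0.880 ± 0.139. Among the largest differences in the other direction were the ligand Bmp5 at −8.37 ± 0.66 (no read in Gli1 cells, at least 1550-fold lower), Acap1, a GTPase activator of endosomes, at −7.97 ± 0.72, and the angiopoietin-like Angptl6 at −7.91 ± 0.60. After them came the macrophage growth factor Il34 at −7.65 ± 0.90, the complement protease Masp1 at −7.41 ± 1.02, the erythropoietin receptor Epor at −7.17 ± 0.76 and the acyltransferase Gpat2 at −6.99 ± 0.92. Adjusted p reached 0.00337 at most among them. Acap1 had 2 reads in all in Gli1 cells, a ratio of 4000 (95% counting interval 1110 to 33000).

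In the mm10 genome, Dpt (ENSMUSG00000026574.5) lies on chromosome 1 from 164796644 to 164824266, Lrat (ENSMUSG00000028003.6) on chromosome 3 from 82892579 to 82903973, and Gli1 (ENSMUSG00000025407.6) on chromosome 10 from 127329882 to 127341974. Igfbp6 (ENSMUSG00000023046.6) lies on chromosome 15 from 102144362 to 102149511 and C3 (ENSMUSG00000024164.15) on chromosome 17 from 57203970 to 57228136.

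Hepatic stellate cell markers were lower in Gli1 cells for 20 of 22 members over all genes and for 21 adjusted over the list alone, with a median of −5.42 (camera adjusted p = 4.2e-33; adjusted p = 0.092 with an estimated correlation). Examples are the matrix signal Reln at −6.63 ± 0.43, the collectin Colec10 at −6.03 ± 0.43, the growth factor Hgf at −6.51 ± 0.65 and the intermediate filament Des at −2.23 ± 0.38. The matrix protein Ecm1 averaged 35870 ± 7983 CPM in stellate cells and 1185 ± 399 CPM in Gli1 cells. Adamtsl2 at −2.48 (adjusted p = 0.0765) and Nes at −1.77 (0.246) did not pass. Portal fibroblast markers were higher for 16 of 19 over all genes and for 18 adjusted over the list alone, with a median of 6.71 (camera adjusted p = 1.3e-19; adjusted p = 0.092 with an estimated correlation). Among them were Pi16 at 9.25 ± 0.67, the sialomucin Cd34 at 8.36 ± 0.71, the elastic fibre proteins Mfap4 at 7.0 ± 0.70 and Fbln2 at 8.16 ± 0.52, and the surface protein Thy1 at 4.95 ± 0.65, whose ratio from few stellate reads was 375 (128 to 1820).

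Some niche ligands differed, but bile duct and mesothelial RNA in Gli1 libraries (below) was not tested as their source. Rspo1, which raises Wnt signalling, averaged 314 ± 27.1 CPM in Gli1 cells and 0.139 ± 0.0241 in stellate cells (8.11 ± 0.58). Its relative Rspo3 averaged 30.5 ± 22.4 CPM and 918 ± 3.08 CPM (−5.08 ± 0.53). The Wnt inhibitors Sfrp1 at 7.93 ± 0.69 and Sfrp4 at 7.39 ± 0.76 were higher in Gli1 cells and Frzb at −6.83 was lower. Wnt and R-spondin genes were higher for 8 and lower for 2 of 16 over all genes, 9 and 2 adjusted over the list alone, with a median of 2.30 (camera adjusted p = 0.015; adjusted p = 0.27 with an estimated correlation). Epithelial niche ligands had 3 of 15 higher and 2 lower, also adjusted over the list alone (median −0.14, camera adjusted p = 0.48). Fgf18 was 4.12 and Fgf7 4.57. Hedgehog genes had 7 of 16 higher and 2 lower (adjusted over the list alone 9 and 3, median 2.30, camera adjusted p = 0.14). The ligand Shh (4.84 ± 0.74, at least 184-fold), the transducer Smo (4.82 ± 0.73) and the co-receptor Cdon (5.31 ± 0.67) were higher in Gli1 cells and the inhibitor Hhip was lower (−6.23 ± 0.59).

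Of the matrix and contractile lists elastic fibre genes passed and the others did not. Smooth muscle actin Acta2 averaged 642 ± 191 CPM against 13.6 ± 3.52 (5.45 ± 0.48), collagen I, Col1a1, 2493 ± 463 CPM against 266 ± 112 (3.28 ± 0.39), and the protease inhibitor Timp1 204 ± 191 CPM against 1.13 ± 1.35 (6.34 ± 0.83). Elastic fibre genes, with elastin, Eln, at 4.52 ± 0.54, were higher for 6 and lower for 1 of 12 over all genes, 7 and 1 adjusted over the list alone (median 1.44, camera adjusted p = 0.0024; adjusted p = 0.43 with an estimated correlation). Contractile genes had 4 of 14 higher and 2 lower (adjusted over the list alone 6 and 2, median 0.68, camera adjusted p = 0.33), among them the calponin Cnn1 at 5.44 ± 0.81. Fibrillar collagens and collagen processing had 8 of 18 higher and 1 lower (adjusted over the list alone 9 and 3, median 0.65, camera adjusted p = 0.14). The crosslinking enzyme Lox was 5.56. Myofibroblast secreted genes had 5 of 16 higher and 2 lower (adjusted over the list alone 6 and 3, median 0.51, camera adjusted p = 0.24). Examples were osteopontin, Spp1, at 7.82 and the proteoglycan Bgn at −1.64 ± 0.23. Basement membrane genes had 5 of 15 higher and 1 lower (adjusted over the list alone 7 and 3, median 0.91, camera adjusted p = 0.25). The laminin Lama4 was 5.56. Genes of TGF-beta had 4 of 17 higher and 2 lower (adjusted over the list alone 7 and 3, median −0.00, camera adjusted p = 0.86), and the target Tgfbi was −3.71 ± 0.42. The PDGF pathway had 0 of 6 higher and 1 lower (adjusted over the list alone 2 and 1, median 1.12, camera adjusted p = 0.99). The PDGF receptor Pdgfrb was lower in Gli1 cells (−2.47 ± 0.51, adjusted p = 0.0196) and Pdgfra was −0.74 ± 0.37 (adjusted p = 0.283).

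Smooth muscle and pericyte markers were lower in Gli1 cells for 4 and higher for 1 of 11 over all genes (adjusted over the list alone 4 and 1, median −0.77, camera adjusted p = 0.015; adjusted p = 0.43 with an estimated correlation, in this order below). The pericyte regulator Rgs5 was −5.99 ± 0.62, the channel subunit Abcc9 −4.54 ± 0.43 and the smooth muscle myosin Myh11 3.55 ± 0.64. Interferon response genes were lower for 4 and higher for 1 of 19 over all genes, 5 and 1 adjusted over the list alone, with a median of −1.24 (2.5e-05; 0.43). Ifit3 was −3.50 ± 0.46 and Usp18 −3.63 ± 0.71, and Gbp2 was 2.60 ± 0.53. Complement genes were higher for 4 of 11 over all genes and 6 adjusted over the list alone (median 1.25, 0.0016; 0.43). The pore protein C7 was 5.48 ± 0.77. Cell cycle genes were higher for 4 of 26 over all genes (adjusted over the list alone 4, median 1.31, 0.031; 0.67). Ccnd1 was 1.57 ± 0.40, and Mki67 at 1.64 ± 0.69 did not pass (adjusted p = 0.199). Retinoid handling genes had 1 of 14 higher and 4 lower (adjusted over the list alone 2 and 6, median −0.28, camera adjusted p = 0.068). The retinoic acid synthase Aldh1a2 was 6.81 ± 0.71. Cytokines and chemokines had 5 of 21 higher and 2 lower (adjusted over the list alone 5 and 2, median 0.39, camera adjusted p = 0.42). The eotaxin Ccl11 was 5.80. Immediate early genes had 1 of 20 higher, Egr1 at 1.72 ± 0.37 (adjusted over the list alone 1, median 0.65, camera adjusted p = 0.31). Unfolded protein response genes and cholesterol synthesis genes had 0 of 15 called each over all genes and 0 adjusted over the list alone (medians −0.45 and 0.54, camera adjusted p = 0.078 and 0.27). The mean of TGF-beta genes was 0.63, although camera's direction for them was down.

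Markers of bile duct epithelium and mesothelium were high in both uninjured Gli1 libraries. All 8 mesothelial markers were higher over all genes and adjusted over the list alone (median 8.24, camera adjusted p = 6.9e-12; adjusted p = 0.23 with an estimated correlation). Examples were Msln at 768 and 2532 CPM in uninjured Gli1 libraries 1 and 2 and Upk3b at 732 and 1442 CPM. Cholangiocyte markers were higher for 7 of 13 over all genes and 10 adjusted over the list alone (median 3.13, camera adjusted p = 1.2e-08; adjusted p = 0.27 with an estimated correlation). The adhesion protein Epcam was at 211 and 172 CPM, with a ratio of 3330 (920 to 27500). Endothelial markers were higher for 2 of 17 (adjusted over the list alone 2, median 1.05, camera adjusted p = 0.15), the clotting factor Vwf at 3.96 ± 0.71 and the hyaluronan receptor Lyve1 at 3.57 ± 0.90. Hepatocyte markers had 1 of 18 higher, the thyroxine carrier Ttr at 4.31 ± 0.92 (adjusted over the list alone 1, median 1.05, camera adjusted p = 0.26). Macrophage markers had 1 of 14 lower, Fcna at −4.78 ± 0.51 (adjusted over the list alone 1, camera adjusted p = 0.71, direction down although the median was 1.05), and Clec4f varied from 2185 to 4.48 CPM between stellate libraries 1 and 2. Schwann cell markers had 1 of 5 higher, Ncam1 at 4.85, and 1 lower, Gfap at −4.12 (adjusted over the list alone 2 and 1, median 0.90, camera adjusted p = 0.40). Lymphocyte and neutrophil markers had 0 of 8 called (adjusted over the list alone 0, median −1.03, camera adjusted p = 0.38), and of erythroid genes only Alas2 was tested (−0.39, adjusted p = 0.843). With genes without reads placed at their bound, fitted medians moved from 3.43 to 5.98 for cholangiocyte markers, from 2.60 to 3.70 for Wnt genes and from 2.60 to 2.92 for Hedgehog genes. They moved from 7.0 to 7.23 for portal fibroblast markers, from 1.61 to 1.66 for cell cycle genes, from 1.2 to 3.30 for Schwann cell markers and from −0.73 to −0.97 for lymphocyte and neutrophil markers.

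The 1771 calls became 3053 with DESeq2, 327 with limma-voom with sample weights (42.5% higher against 72.8%) and 1548 without weights, 353 in a fit of the 2 groups alone, and 554 without uninjured stellate library 1 and ligated Gli1 library 2. Single libraries left out gave 1002, 1176, 1103 and 1116 without uninjured Gli1 library 1, ligated Gli1 library 2 and ligated stellate libraries 1 and 2, and cell cycle genes lost their call without uninjured Gli1 library 2 (adjusted p = 0.79) and smooth muscle and pericyte markers without uninjured stellate library 2 (0.16).

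**Figure D1:**
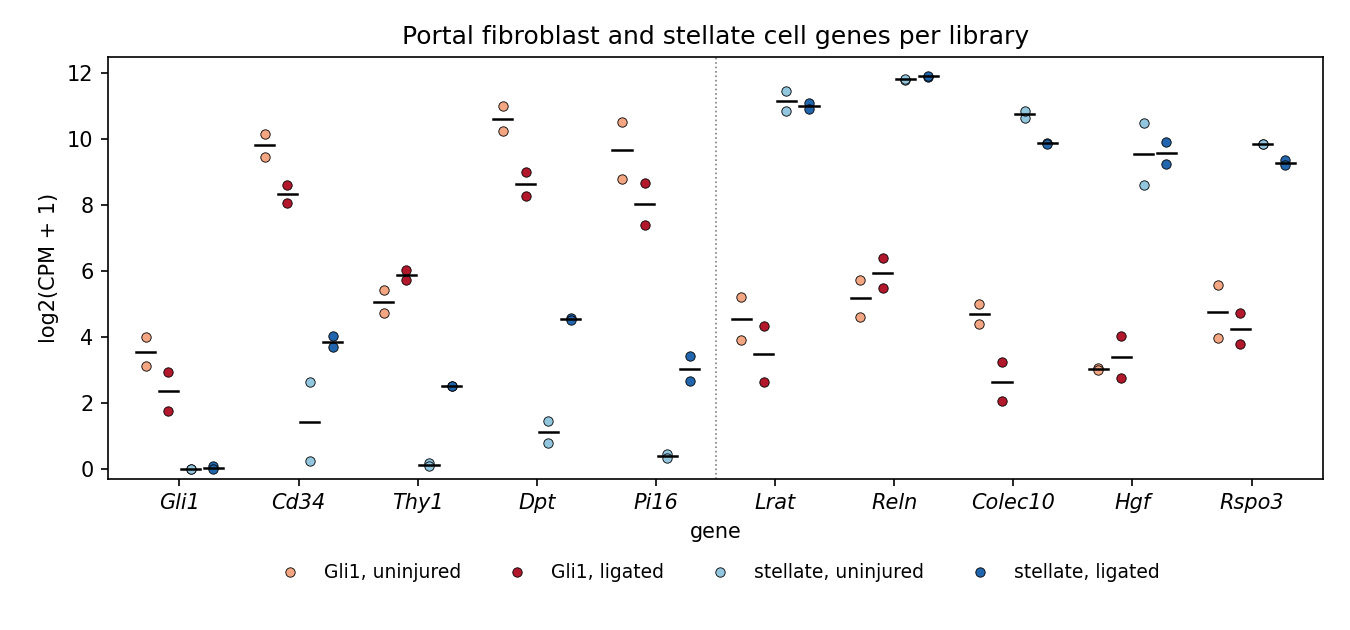
Levels of 10 genes as log2(CPM + 1) on the vertical axis in Gli1 and stellate cells, uninjured and ligated, where dots are libraries and bars their mean. In uninjured Gli1 cells Cd34 averaged 915 CPM and Dpt 1608 CPM against 2.67 and 1.23 CPM in stellate cells, and Lrat and Reln averaged 2308 and 3549 CPM in stellate cells against 24.8 and 37.6 CPM.

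After ligation the same question was asked of the injured liver. Stellate cell markers and portal fibroblast markers again set the cell types apart, and portal fibroblast markers differed by less than before (interaction, camera adjusted p = 2.8e-11; adjusted p = 0.23 with an estimated correlation). Dpt averaged 404 ± 141 CPM in Gli1 cells and 22.3 ± 0.906 CPM in stellate cells, a log2 difference of 4.07 ± 0.43 (adjusted p = 0.00194). Lrat averaged 12.2 ± 9.98 CPM and 2034 ± 179 CPM (−7.51 ± 0.61, adjusted p = 0.000879). Gli1 at 4.5 ± 2.98 CPM against 0.0292 ± 0.0413 did not pass over all genes (2.30 ± 0.72, adjusted p = 0.111) and passed adjusted over the list alone (0.0277), with a ratio of 121 (21.3 to 4820).

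Differences were called for 1083 genes, 709 higher and 374 lower in Gli1 cells. Those called higher in both states numbered 466, against 52.3 for chance, and those lower in both 261, against 10.3 (Fisher's exact test, −log10 p = 375 and 347). Log2 differences of the 2 states correlated at 0.67 across genes, which are not independent replicates. Only 1 gene was called in opposite directions, the early response factor Egr1, at 1.72 ± 0.37 (adjusted p = 0.0227) before and −1.81 ± 0.37 (adjusted p = 0.0249) after ligation. Both calls were lost with edgeR (adjusted p = 0.103 and 0.0591) and with a library left out (up to 0.113 and 0.228). Egr1 (ENSMUSG00000038418.7, chromosome 18 from 34859823 to 34864984) averaged 652 ± 120 CPM in uninjured Gli1 cells, 199 ± 59.5 in uninjured stellate cells, 218 ± 63.4 in ligated Gli1 cells and 772 ± 240 in ligated stellate cells.

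Among the largest differences upward were epithelial and mesothelial genes: Krt19 at 9.33 ± 0.53, Dmbt1 at 9.23 ± 0.74, Msln at 8.95 ± 0.58, Krt7 at 8.67 ± 0.64, Epcam at 8.65 ± 0.58 and the surface protein Cd24a at 8.59 ± 0.75. The pancreatitis-related lectin Reg1 was 8.80 ± 0.80 and the surface protein Ly6d 8.51 ± 1.11. Adjusted p among these 8 was 0.00458 at most. The largest differences downward were Lrat, Colec10 at −7.22 ± 0.43, the von Willebrand factor protease Adamts13 at −7.15 ± 0.75, Colec11 at −6.94 ± 0.70, the neurotrophin receptor Ngfr at −6.78 ± 0.59, Angptl6 at −6.77 ± 0.60 and the peptide receptor Vipr1 at −6.72 ± 0.75. The ligand Gdf2 at −6.69 ± 0.47 averaged 14.2 CPM in Gli1 cells and 1450 ± 207 CPM in stellate cells. Their adjusted p was 0.00238 at most.

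Hepatic stellate cell markers were lower in Gli1 cells for 21 of 22 over all genes and 22 adjusted over the list alone (median −5.37, camera adjusted p = 4.2e-38; adjusted p = 0.079 with an estimated correlation, in this order below). Examples were Reln at −5.95 ± 0.43 and Des at −2.40 ± 0.38. Portal fibroblast markers were higher for 12 of 19 over all genes and 15 adjusted over the list alone (median 3.64, 1.1e-12; 0.12). Among them were Igfbp6 at 7.72 ± 0.41, Mfap5 at 7.83 and Cd34 at 4.48 ± 0.71. Elastic fibre genes were higher for 6 and lower for 1 of 12, 8 and 2 adjusted over the list alone (median 1.40, 0.014; 0.47). Members included the fibrillin Fbn2 at 6.66 ± 0.80 and Emilin1 at −3.40. Smooth muscle and pericyte markers were lower for 4 of 11 over all genes and 5 adjusted over the list alone (median −1.13, 0.00028; 0.18). Examples were Abcc9 at −4.79 ± 0.43 and Rgs5 at −4.92 ± 0.62.

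Interferon response and immediate early genes were lower in ligated Gli1 cells than in ligated stellate cells, and cholesterol synthesis genes higher. Interferon response genes were lower for 4 of 19 over all genes and 8 adjusted over the list alone (median −1.95, camera adjusted p = 3.4e-10; adjusted p = 0.20 with an estimated correlation, in this order below). Among them were Ifit3 at −4.34 ± 0.46, the ubiquitin-like Isg15 at −3.23 ± 0.63 and B2m, the light chain of class I molecules, at −1.73 ± 0.34. Immediate early genes were lower for 3 of 20 over all genes, and for 9 with 1 higher adjusted over the list alone (median −1.57, 6.6e-06; 0.14). Members included Ier2 at −1.52 ± 0.32 and the mRNA decay factor Zfp36 at −1.92 ± 0.44. Cholesterol synthesis genes were higher for 2 of 15 over all genes and 6 adjusted over the list alone (median 1.32, 0.00028; 0.12). Examples were the synthase Hmgcs1 at 2.5 ± 0.38 and the demethylase Cyp51 at 1.82 ± 0.43. Cell cycle genes had 0 of 26 called over all genes and 0 adjusted over the list alone (median 0.99, 0.025; 0.69). Mki67 was 1.30 (adjusted p = 0.381).

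Cholangiocyte markers were higher in ligated Gli1 cells for 12 of 13 over all genes and 13 adjusted over the list alone (median 5.58, camera adjusted p = 1.5e-14; adjusted p = 0.12 with an estimated correlation, in this order below). Mesothelial markers were higher for 8 of 8 over all genes and 8 adjusted over the list alone (median 6.76, 8.4e-13; 0.12). Epcam was 1077 and 458 CPM in ligated Gli1 libraries 1 and 2 against 0.467 and 1.10 CPM in stellate libraries. Hepatocyte markers had 0 of 18 called (adjusted over the list alone 0, median 1.72, 0.00071; 0.65), and albumin, Alb, was 990 and 5648 CPM in Gli1 libraries against 651 and 450 CPM. Endothelial markers had 1 of 17 higher, Vwf at 3.54 ± 0.71 (adjusted over the list alone 1 higher and 1 lower, median −1.14, 0.011; 0.69). Macrophage markers had 1 of 14 lower, Fcna at −3.50 (adjusted over the list alone 1, camera adjusted p = 0.97, direction down, or up with TMM scaling, with a median of 0.66). Lymphocyte and neutrophil markers had 0 of 8 called (adjusted over the list alone 0, median 0.53, camera adjusted p = 0.82). Schwann cell markers had 1 of 5 higher, S100b at 4.80 (adjusted over the list alone 2 higher and 1 lower, median 0.30, camera adjusted p = 0.76), and Alas2 was 0.55 (adjusted p = 0.83).

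The remaining lists did not separate the ligated cell types as wholes. Col1a1 was higher in Gli1 cells (1.89 ± 0.39, adjusted p = 0.0267), Acta2 was 1.91 ± 0.48 (0.055) and Timp1 1.73 ± 0.83 (0.318). Fibrillar collagens and collagen processing had 2 of 18 higher and 1 lower (adjusted over the list alone 5 and 5, median −0.05, camera adjusted p = 0.82). Contractile genes had 2 of 14 higher and 1 lower (adjusted over the list alone 4 and 1, median −0.15, camera adjusted p = 0.97). Myofibroblast secreted genes had 2 of 16 higher and 1 lower (adjusted over the list alone 4 and 2, median 0.79, camera adjusted p = 0.76). Basement membrane genes had 3 of 15 higher and 1 lower (adjusted over the list alone 7 and 4, median −0.89, camera adjusted p = 0.82). Members included Col4a5 at 4.56 and Lamb1 at −2.66. Genes of TGF-beta had 3 of 17 higher and 2 lower (adjusted over the list alone 3 and 3, median −0.37, camera adjusted p = 0.22). The integrin Itgb6 was 5.06 ± 0.86 (at least 155-fold). The PDGF pathway had 2 of 6 lower, Pdgfra at −1.78 ± 0.37 and Pdgfrb at −2.68 ± 0.51 (adjusted over the list alone 2 higher and 2 lower, median 1.14, camera adjusted p = 0.99). Hedgehog genes had 2 of 16 higher, Gli2 at 3.07 ± 0.66 and Gas1 at 2.76 ± 0.59, and 2 lower, Foxf1 at −3.07 ± 0.45 and Hhip at −6.07 ± 0.59 (adjusted over the list alone 7 and 4, median 0.83, camera adjusted p = 0.82). Wnt and R-spondin genes had 4 of 16 higher and 3 lower (adjusted over the list alone 8 and 3, median 1.63, camera adjusted p = 0.31). Among them were Rspo1 at 6.44 ± 0.58, the inhibitor Wif1 at 4.62 ± 0.67 and Rspo3 at −5.03 ± 0.53. Epithelial niche ligands had 2 of 15 lower, Hgf at −6.18 ± 0.65 and Bmp5 at −5.09 (adjusted over the list alone 4 higher and 3 lower, median −0.44, camera adjusted p = 0.22). Complement genes had 1 of 11 higher, C3 at 4.60 ± 0.61, and 1 lower, the inhibitor Serping1 at −1.19 ± 0.28 (adjusted over the list alone 1 and 1, camera adjusted p = 0.97, direction down although the median was 0.16). Retinoid handling genes had 2 of 14 higher and 2 lower (adjusted over the list alone 3 and 5, median −1.21, camera adjusted p = 0.096). The retinoic acid hydroxylase Cyp26a1 was 4.24, with a ratio of 328 (90.3 to 2710). Cytokines and chemokines had 3 of 21 higher and 2 lower (adjusted over the list alone 3 and 3, median −0.50, camera adjusted p = 0.33). The iron carrier Lcn2 was 5.30 and Cxcl14 −2.28. Unfolded protein response genes had 0 of 15 called (adjusted over the list alone 0, median −0.32, camera adjusted p = 0.25). Camera's direction was down although the mean was 0.62 for basement membrane genes, 0.53 for contractile genes, 0.46 for cytokines and chemokines, 0.24 for fibrillar collagens and 0.11 for TGF-beta genes. At their bound, fitted medians moved from 5.81 to 6.99 for cholangiocyte markers, from 1.02 to 1.47 for myofibroblast secreted genes, from 0.76 to 1.32 for lymphocyte and neutrophil markers and from 0.53 to 1.26 for Schwann cell markers.

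The 1083 calls became 1687 with DESeq2, 1850 and 665 with limma-voom with and without sample weights, 1835 in a fit of the 2 groups alone, 624 with edgeR (54.8% higher against 65.5%), and 114 (40.4% higher) without uninjured stellate library 1 and ligated Gli1 library 2. Single libraries left out gave 151 and 378 without ligated Gli1 libraries 1 and 2, and 152 and 198 without ligated stellate libraries 1 and 2, and list calls were lost by hepatocyte markers (adjusted p = 0.64) and elastic fibre genes (0.09) without ligated Gli1 library 2, and by endothelial markers (0.23) and cell cycle genes (0.3) without ligated Gli1 library 1.

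**Figure D2:**
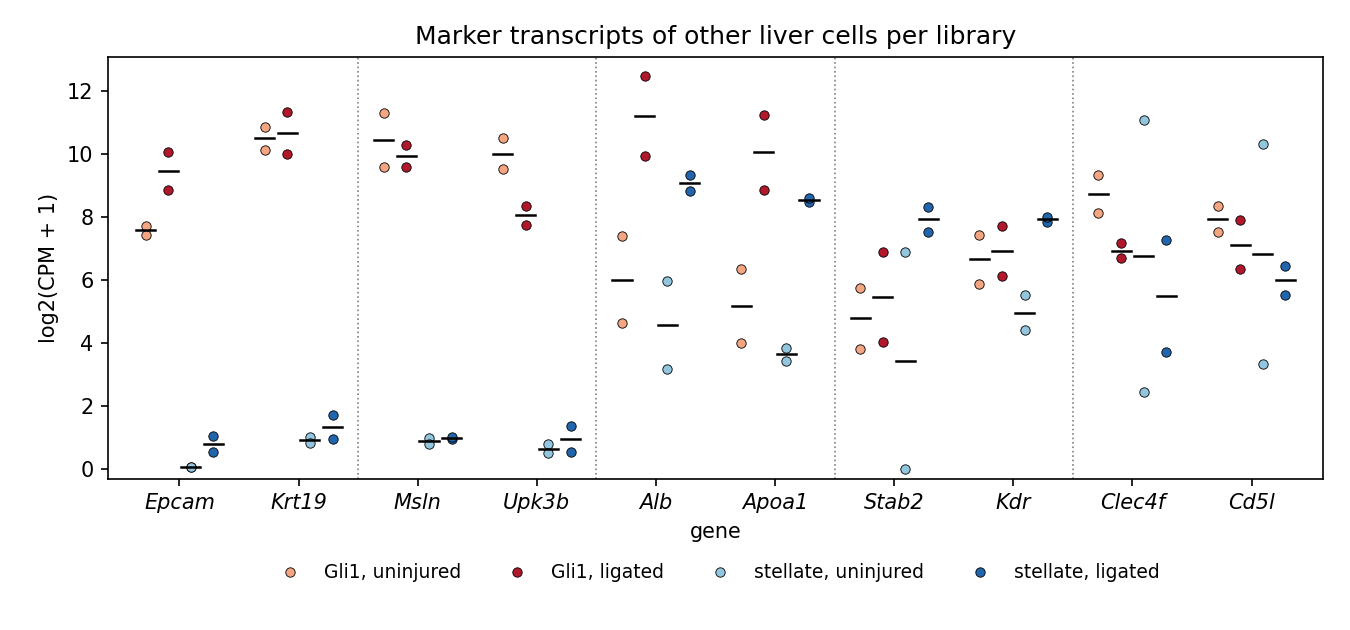
Levels of 10 marker genes of other liver cells as log2(CPM + 1) on the vertical axis in the 4 groups, where dots are libraries and bars their mean. Epcam and Krt19 of bile duct epithelium and Msln and Upk3b of mesothelium were high in Gli1 libraries, Alb of hepatocytes reached 5648 CPM in ligated Gli1 library 2, and Clec4f of macrophages was 2185 CPM in uninjured stellate library 1 against 4.48 CPM in library 2.

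The next comparison asked how Gli1 cells respond to ligation. No gene passed over all genes with limma at 17461 tested, although 1919 had an unadjusted p below 0.05. Genes of the portal fibroblast, interferon and complement lists were lower after ligation as groups, and hepatocyte, cholesterol synthesis and cell cycle genes higher (adjusted p = 0.19 to 0.35 with an estimated correlation). Of these, complement and cell cycle genes lost their call without 1 library (below). Gsn (ENSMUSG00000026879.14, chromosome 2 from 35256380 to 35307892), which severs actin filaments, averaged 9831 ± 6429 CPM before and 629 ± 111 CPM after ligation (−3.80 ± 0.44, adjusted p = 0.0584). Reg3b (ENSMUSG00000071356.7, chromosome 6 from 78370657 to 78373466), an antibacterial lectin, averaged 0.235 ± 0.170 CPM before and 441 ± 328 CPM after (8.26 ± 0.80, adjusted p = 0.0584).

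The other genes with the smallest p, none of which passed, were all at an adjusted p of 0.0584. Those with more RNA after ligation were the thrombin inhibitor Serpinc1 at 6.85 ± 0.85, the phospholipase Pla2g2f at 5.08 ± 0.58 (at least 150-fold), the ciliary protein Dcdc2a at 4.26 ± 0.54 and the epithelial Trim29 at 3.59 ± 0.50 (at least 50.6-fold). Those with less were the peptide amidating enzyme Pam at −3.22 ± 0.34, the growth factor signal inhibitor Spry2 at −2.89 ± 0.32, the zinc carrier Slc39a1 at −2.62 ± 0.34 and the RNA demethylase Alkbh5 at −2.31 ± 0.31. Gli1 was −1.20 ± 0.72 (adjusted p = 0.643), Col1a1 1.02 ± 0.39 (0.378), Acta2 0.35 ± 0.48 (0.886), Timp1 2.24 ± 0.83 (0.353), Thy1 0.81 (0.772) and Mki67 1.84 ± 0.69 (0.36). With edgeR 0 genes were called (1303 at an unadjusted p below 0.05), with DESeq2 422, with limma-voom 4 with sample weights and 0 without, with the stricter filter 11, without a filter 4 and with 4 CPM added 45.

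Portal fibroblast markers fell as a list, with 0 of 19 called over all genes and 5 lower adjusted over the list alone (median −1.51, camera adjusted p = 5.8e-07; adjusted p = 0.26 with an estimated correlation). Dpt at −1.99 ± 0.43, Igfbp6 at −1.92 ± 0.41 and the plasminogen binding lectin Clec3b at −4.87 ± 0.77 were among the 5. Interferon response genes had 0 of 19 called and 3 lower adjusted over the list alone (median −1.33, camera adjusted p = 2.8e-09; adjusted p = 0.26 with an estimated correlation), Ifit3 at −1.80 ± 0.46, Gbp2 at −2.43 ± 0.53 and B2m at −1.21 ± 0.34. Complement genes had 0 of 11 called and 3 lower adjusted over the list alone (median −1.36, camera adjusted p = 1.0e-05; adjusted p = 0.26 with an estimated correlation), C1ra at −1.65 ± 0.37, Serping1 at −1.35 ± 0.28 and C7 at −2.47. Immediate early genes had 0 of 20 called and 1 lower adjusted over the list alone, Egr1 at −1.60 ± 0.37 (median −1.17, camera adjusted p = 3.1e-06; adjusted p = 0.26 with an estimated correlation). Hedgehog genes had 0 of 16 called and 2 lower adjusted over the list alone, Shh at −3.84 ± 0.74 and its target Foxf1 at −1.68 ± 0.45 (median −0.79, camera adjusted p = 0.00041; adjusted p = 0.27 with an estimated correlation). Wnt and R-spondin genes had 0 of 16 called, with Wif1 at 3.98 ± 0.67 and Frzb at 4.23 ± 0.74 higher adjusted over the list alone. Sfrp4 at −2.58 and Wnt11 at −2.38 were lower (median −0.82, camera adjusted p = 0.025; adjusted p = 0.26 with an estimated correlation). Stellate cell markers had 0 of 22 called, and 1 higher and 2 lower adjusted over the list alone, with Colec10 at −2.06 (median −0.87, camera adjusted p = 0.00023; adjusted p = 0.35 with an estimated correlation).

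Cholesterol synthesis genes rose as a list, with 0 of 15 called over all genes and 7 higher adjusted over the list alone (median 1.46, camera adjusted p = 3.1e-07; adjusted p = 0.19 with an estimated correlation). Hmgcs1 (ENSMUSG00000093930.1, chromosome 13 from 119690379 to 119708260) averaged 71.1 ± 21.4 CPM before and 325 ± 78.4 CPM after ligation (2.19 ± 0.38, adjusted p = 0.0714), and Cyp51 and the epoxidase Sqle were 2.41 ± 0.43 and 3.01 ± 0.58. Cell cycle genes had 0 of 26 called and 0 adjusted over the list alone, with 24 above 0 (median 1.63, camera adjusted p = 9.2e-06; adjusted p = 0.35 with an estimated correlation). Hepatocyte markers had 0 of 18 called and 15 higher adjusted over the list alone (median 4.43, camera adjusted p = 1.8e-14; adjusted p = 0.26 with an estimated correlation). Examples were Cyp3a11 at 7.60 ± 1.10 and Apoa1 at 4.88 ± 0.87, which averaged 1449 ± 1386 CPM after ligation. RNA of other cells was not tested as a source of Serpinc1, Reg3b, Trim29 or cell cycle genes. Cholangiocyte markers had 0 of 13 called and 0 adjusted over the list alone, with all 13 above 0 (median 1.49, camera adjusted p = 0.00034; adjusted p = 0.35 with an estimated correlation), and Epcam was 1.88 ± 0.58 (adjusted p = 0.248). Mesothelial markers had 0 of 8 called and 0 adjusted over the list alone, with none above 0 (median −1.38, camera adjusted p = 0.00041; adjusted p = 0.35 with an estimated correlation), and Upk3b was −1.95 ± 0.54 (adjusted p = 0.2).

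The remaining lists did not pass in Gli1 cells and had 0 members called over all genes. Adjusted over the list alone, myofibroblast secreted genes had 3 higher, the matrix proteins Tnc at 2.84 ± 0.65, Cthrc1 at 4.24 ± 1.01 and Spp1 at 3.29 ± 0.97, and 1 lower, Grem1 at −2.90 ± 0.68 (median 0.37, camera adjusted p = 0.13). Basement membrane genes had Col4a1 at 1.59 ± 0.28 and Col4a2 at 1.42 ± 0.32 higher adjusted over the list alone (median −0.11, camera adjusted p = 0.81, direction up). Elastic fibre genes had Fbn2 at 5.48 ± 0.80 higher and Ltbp4 at −1.65 lower adjusted over the list alone (median −0.16, camera adjusted p = 0.72). Genes of TGF-beta had the receptor Tgfbr3 at −1.72 ± 0.32 lower (adjusted over the list alone 1, median −0.07, camera adjusted p = 0.81, direction up). Retinoid handling genes had 3 higher adjusted over the list alone, with Cyp26a1 at 4.32 ± 0.64 (at least 97.0-fold; camera adjusted p = 0.72, direction up although the median was −0.34). Cytokines and chemokines had 3 higher and 1 lower adjusted over the list alone, with Il11 at 2.41 and Cxcl10 at −2.71 (median −0.17, camera adjusted p = 0.81). Epithelial niche ligands had 3 and 3, with Nrg1 at 2.04 and Fgf7 at −3.29 (median −0.40, camera adjusted p = 0.35). None passed adjusted over the list alone among fibrillar collagens and collagen processing (median 0.20, camera adjusted p = 0.81), contractile genes (0.07, 0.95), the PDGF pathway (0.31, 0.81), and unfolded protein response genes (−0.13, 0.81). The same held for markers of endothelium (0.55, 0.12), macrophages (−0.48, 0.66), lymphocytes and neutrophils (0.28, 0.82), smooth muscle and pericytes (−0.45, 0.38) and Schwann cells (−0.10, 0.96). Alas2 was 0.86 (adjusted p = 0.818). Means of 0.28 for elastic fibre genes, 0.25 for cytokines and chemokines and 0.20 for Schwann cell markers stood beside a camera direction of down.

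List calls were lost without ligated Gli1 library 1 by stellate cell markers (adjusted p = 0.12), complement (0.052), Wnt (0.31) and cholangiocyte genes (0.12), without uninjured Gli1 library 1 by cell cycle genes (0.05) and without uninjured Gli1 library 2 by mesothelial markers (0.38).

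**Figure D3:**
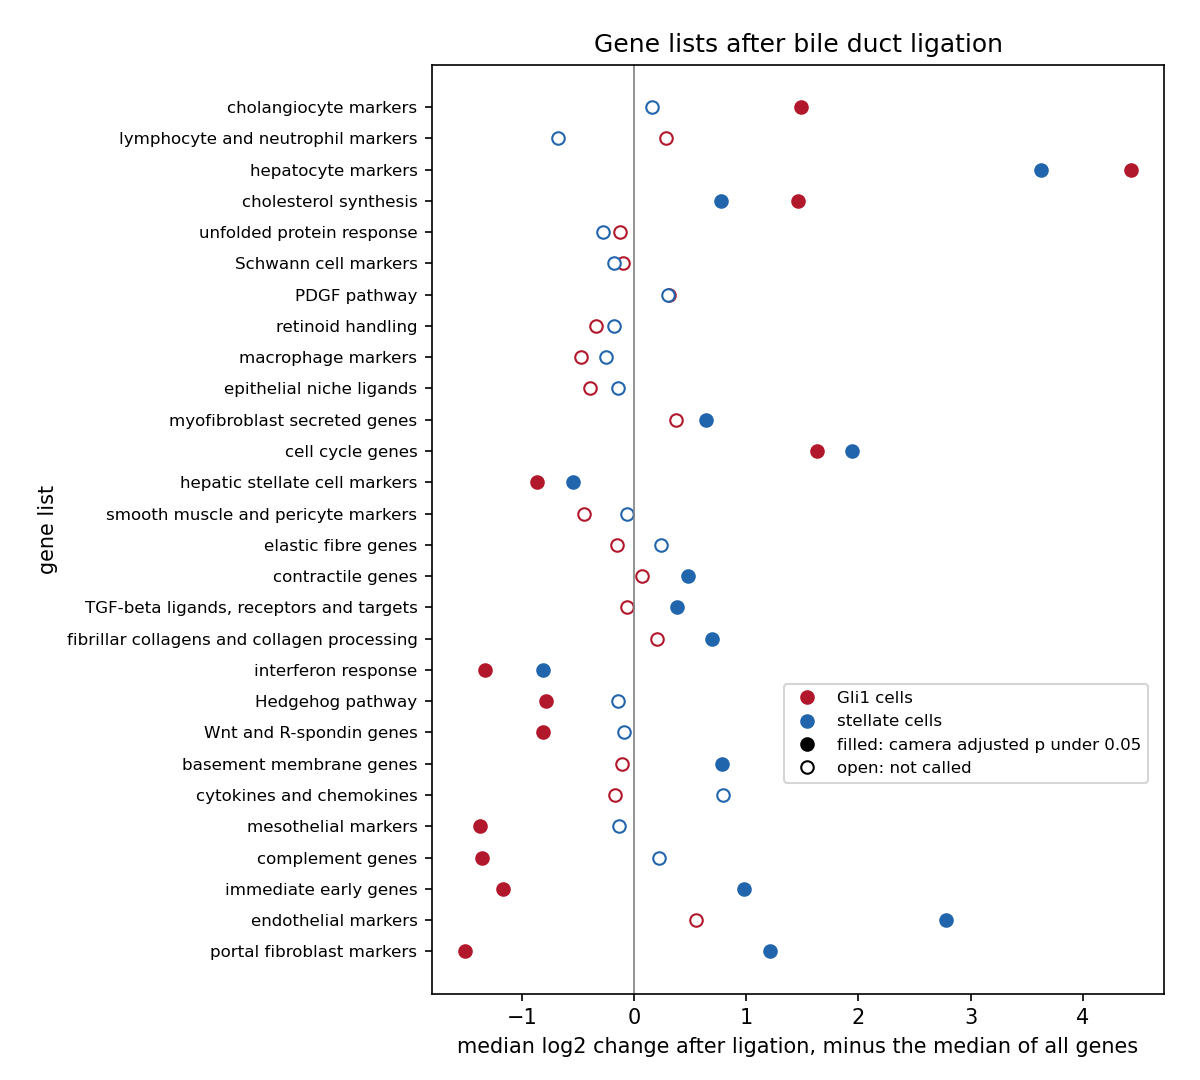
Change of each gene list after ligation as the median log2 change of its members minus that of all genes, on the horizontal axis, in Gli1 cells (red) and stellate cells (blue), filled where camera called the list and open where it did not. Portal fibroblast markers stood at −1.51 in Gli1 cells and 1.21 in stellate cells, and endothelial markers at 0.55 and 2.78.

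The same question was asked of stellate cells. Ligation raised 34 genes and lowered none, with 1999 genes at an unadjusted p below 0.05. They included the contractile gene Acta2, the protease inhibitor Timp1 and the portal fibroblast marker Dpt. Among lists endothelial markers had the lowest camera adjusted p, with 0 of 17 called over all genes and all 17 above 0 (median 2.78, camera adjusted p = 1.7e-10; adjusted p = 0.37 with an estimated correlation). Slco2a1 (ENSMUSG00000032548.14, chromosome 9 from 102988712 to 103096002), a prostaglandin carrier, rose from 0.0782 ± 0.111 to 125 ± 24.6 CPM (6.85 ± 0.41, adjusted p = 0.00151; ratio 1510, interval 517 to 7340). Plat (ENSMUSG00000031538.6, chromosome 8 from 22757727 to 22782844), the tissue plasminogen activator, rose from 0.0827 ± 0.0305 to 127 ± 57.4 CPM (6.80 ± 0.45, adjusted p = 0.00212; ratio 1410, interval 482 to 6840).

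The other large rises were the acute phase haptoglobin Hp at 7.57 ± 0.78, the protease inhibitor Serpina3n at 7.12 ± 0.55 (ENSMUSG00000021091.8, chromosome 12 from 104406729 to 104414329) and Timp1 at 6.86 ± 0.83 (ENSMUSG00000001131.11, chromosome X from 20870166 to 20874735). Next came the urinary protein Mup20 at 6.86 ± 0.71, Spp1 at 6.79 ± 0.97 and the junction protein Jam2 at 6.54 ± 0.93. Serpina3n averaged 0.426 ± 0.430 CPM before and 194 ± 23.1 CPM after ligation. Levels of Serpina3n and Mup20 are uncertain, since near-identical copies share reads. Hepatocyte markers rose too (below), and hepatocyte RNA was not tested as a source of Hp and Mup20. Acta2 (ENSMUSG00000035783.8, chromosome 19 from 34241090 to 34255590) rose from 13.6 ± 3.52 to 238 ± 156 CPM (3.88 ± 0.48, adjusted p = 0.0309), and the collagen crosslinking enzyme Loxl2 from 24.8 ± 0.515 to 205 ± 55.4 CPM (2.97 ± 0.35, adjusted p = 0.0279). Dpt rose by 3.42 ± 0.43 and C3 by 4.74 ± 0.61. Lrat at −0.15 ± 0.61, Reln at 0.09, Des at 0.38, Gli1 at 0.04, Pdgfra at 0.32, Pdgfrb at 0.78 and Mki67 at 2.18 ± 0.69 did not pass.

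Beside endothelial and hepatocyte markers, matrix and contractile lists other than elastic fibre genes rose in stellate cells, most only with all libraries (below). Adjusted p was 0.37 with an estimated correlation, unless given. Fibrillar collagens and collagen processing had 1 of 18 called, Loxl2, and 8 higher with 1 lower adjusted over the list alone (median 0.69, camera adjusted p = 0.00053). Col1a1 averaged 266 ± 112 CPM before and 1412 ± 598 CPM after ligation (2.40 ± 0.39, adjusted p = 0.0768), and Col5a2 and Lox were 2.47 ± 0.47 and 4.32 ± 0.78. Myofibroblast secreted genes had 2 of 16 called, Timp1 and Spp1, and 6 higher adjusted over the list alone (median 0.64, camera adjusted p = 0.0025). Fibronectin, Fn1, was 1.73 ± 0.34. Contractile genes had 1 of 14 called, Acta2, and 1 adjusted over the list alone (median 0.48, camera adjusted p = 0.026; adjusted p = 0.44 with an estimated correlation). Basement membrane genes had 0 of 15 called and 4 higher adjusted over the list alone (median 0.78, camera adjusted p = 0.00053). Members included Lama4 at 3.53 ± 0.67 and the proteoglycan Hspg2 at 2.44 ± 0.48. Genes of TGF-beta had 0 of 17 called and 4 higher adjusted over the list alone (median 0.38, camera adjusted p = 0.043; 0.079 with TMM scaling). The integrin Itgav was 1.98 ± 0.38. Portal fibroblast markers had 1 of 19 called, Dpt, and 8 higher adjusted over the list alone (median 1.21, camera adjusted p = 0.00074). Among them were Pi16 at 2.64 ± 0.67 and Thy1 at 2.39.

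Cell cycle genes had 0 of 26 called and 3 higher adjusted over the list alone, Cdk1 at 2.54 ± 0.54, Cenpf at 4.03 ± 0.88 and Plk1 at 3.38 ± 0.69 (median 1.94, camera adjusted p = 1.2e-05; adjusted p = 0.37 with an estimated correlation, as in the next 3 lists). The fitted median moved from 2.13 to 2.16 at its bound. Immediate early genes had 0 of 20 called and 3 higher adjusted over the list alone, Egr1 at 1.94 ± 0.37, Ier3 at 2.04 and the cytokine signal inhibitor Socs3 at 2.26 (median 0.98, camera adjusted p = 0.015). Cholesterol synthesis genes had 0 of 15 called and 0 adjusted over the list alone (median 0.77, camera adjusted p = 0.021). Interferon response genes fell as a list, with 0 of 19 called and 0 adjusted over the list alone (median −0.82, camera adjusted p = 2.8e-05), and Irf7 was −1.78 (adjusted p = 0.443). Stellate cell markers also fell as a list, with 0 of 22 called and 1 lower adjusted over the list alone, Ecm1 at −1.55 ± 0.31 (median −0.55, camera adjusted p = 0.0023; adjusted p = 0.39 with an estimated correlation).

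Endothelial markers had 0 of 17 called and 13 higher adjusted over the list alone, with the list test given above. Lyve1 was 5.51 ± 0.90, the phosphatase Ptprb 5.33 ± 1.01, and the growth factor receptor Kdr 45.4 and 20.2 CPM before against 230 and 258 CPM after ligation. Hepatocyte markers had 0 of 18 called and 12 higher adjusted over the list alone (median 3.63, camera adjusted p = 5.9e-09; adjusted p = 0.37 with an estimated correlation). The fibrinogen Fga was 6.17 ± 0.95, and Alb was 62.0 and 8.13 CPM before against 651 and 450 CPM after ligation. Macrophage markers had 0 of 14 called and 1 lower adjusted over the list alone, Fcna at −2.05 (median −0.25, camera adjusted p = 0.21). They passed as up without uninjured stellate library 1 (3.3e-10) and as down without library 2 (7.2e-17).

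Of the lists that did not pass, complement genes had 1 of 11 called, C3 (adjusted over the list alone 1, median 0.22, camera adjusted p = 0.11), and the others 0. Cytokines and chemokines had 4 higher adjusted over the list alone, with Cxcl1 at 3.11 ± 0.63 and Il11 at 3.15 (median 0.79, camera adjusted p = 0.073). Retinoid handling genes had 3, with Cyp26b1 at 4.05 (median −0.18, camera adjusted p = 0.98, direction up). Wnt and R-spondin genes had 2, Wnt2 at 2.90 and Dkk3 at 1.92 (median −0.09, camera adjusted p = 0.73, direction up). Schwann cell markers had 1, Ncam1 at 2.52 (median −0.18, camera adjusted p = 0.75, direction up). None passed adjusted over the list alone among Hedgehog genes (median −0.15, camera adjusted p = 0.73), elastic fibre genes (0.24, 0.62), the PDGF pathway (0.30, 0.62), epithelial niche ligands (−0.15, 0.62), and unfolded protein response genes (−0.28, 0.21). Nor did any among markers of cholangiocytes (0.16, 0.75), lymphocytes and neutrophils (−0.68, 0.18), mesothelium (−0.14, 0.75) and smooth muscle and pericytes (−0.07, 0.98). Alas2 was −0.08. Means of 0.23 for Hedgehog genes, 0.13 for epithelial niche ligands, 0.12 for mesothelial markers and 0.39 for smooth muscle and pericyte markers stood beside a camera direction of down, which was up with TMM scaling for the last.

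The 34 calls became 1040 with DESeq2 (181 lower), 61 with edgeR, 70 with the stricter filter, 22 with TMM or RLE scaling, 18 with 4 CPM added, 9 without a filter and 0 with limma-voom with or without sample weights, with the 2 groups alone and without uninjured stellate library 1 and ligated Gli1 library 2 together. Single libraries left out gave 0 (ligated stellate 2), 1 (either ligated Gli1), 3 (ligated stellate 1), 10 (either uninjured Gli1), 155, with 25 lower (uninjured stellate 2) and 177, with 4 lower (uninjured stellate 1), so that none of the 34 held throughout. Without uninjured stellate library 1 contractile genes (also with RLE scaling, adjusted p = 0.052), fibrillar collagens and basement membrane genes lost their call. So did TGF-beta genes without ligated stellate library 2, and cholesterol synthesis and immediate early genes without library 1. Stellate cell markers lost theirs without uninjured stellate library 2, and myofibroblast secreted genes without uninjured stellate library 1 and ligated Gli1 library 2 together.

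**Figure D4:**
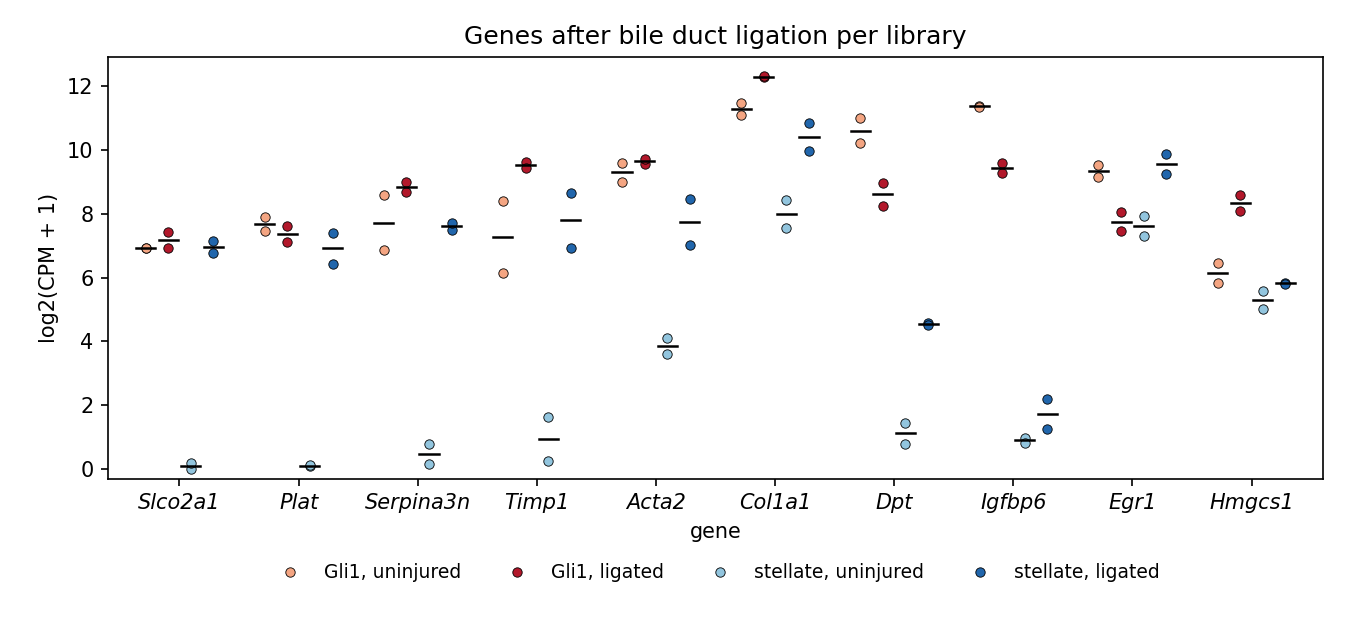
Levels of 10 genes as log2(CPM + 1) on the vertical axis before and after ligation in Gli1 and stellate cells, where dots are libraries and bars their mean. Slco2a1 averaged 0.0782 and 125 CPM in uninjured and ligated stellate cells and 120 and 146 CPM in Gli1 cells, and Dpt averaged 1.23 and 22.3 CPM in stellate cells and 1608 and 404 CPM in Gli1 cells.

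The last comparison asked whether ligation changed Gli1 and stellate cells differently. Plat and Slco2a1 were the 2 genes that passed, at −7.12 ± 0.64 and −6.59 ± 0.58 (adjusted p = 0.0235 for both; edgeR adjusted p = 0.0102 and 0.0331), and 1251 genes had an unadjusted p below 0.05. Plat averaged 207 ± 43.1 and 166 ± 40.5 CPM in uninjured and ligated Gli1 cells, and Slco2a1 120 ± 0.751 and 146 ± 34.8 CPM, so both were already high in Gli1 cells when they were low in stellate cells. Dpt was −5.41 (adjusted p = 0.09), C3 −6.23 ± 0.87 (0.163), Egr1 −3.54 ± 0.52 (0.172) and Timp1 −4.61 ± 1.17 (0.431).

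Portal fibroblast markers changed in opposite directions, with 0 of 19 called over all genes and 9 lower adjusted over the list alone (median −2.54, camera adjusted p = 2.8e-11; adjusted p = 0.23 with an estimated correlation, in this order below). Dpt, Igfbp6 at −2.74 ± 0.58, Pi16 at −4.25 ± 0.95 and Cd34 at −3.88 ± 1.0 were among the 9. Immediate early genes had 0 of 20 called and 4 lower adjusted over the list alone, with Egr1, Socs3 at −2.78 and Ier2 at −1.67 (median −1.73, 8.2e-08; 0.23). Complement genes had 0 of 11 called and 5 lower adjusted over the list alone, with C3 and Serping1 at −1.90 ± 0.40 (median −1.51, 9.6e-06; 0.41). Endothelial markers had 0 of 17 called and 0 adjusted over the list alone (median −2.59, 3.1e-05; 0.52). These 4 lists kept their call whichever library was left out.

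Fibrillar collagens and collagen processing had 0 of 18 called and 1 lower adjusted over the list alone, Loxl2 at −2.72 ± 0.50 (median −0.46, camera adjusted p = 0.0052; adjusted p = 0.52 with an estimated correlation, in this order below). Basement membrane genes had 0 of 15 called and 2 lower adjusted over the list alone, Hspg2 at −2.52 and Lama4 at −3.57 (median −0.47, 0.024; 0.52). Hedgehog genes had 0 of 16 called and 3 lower adjusted over the list alone, Shh at −3.90, Smo at −3.64 and Cdon at −3.22 (median −0.78, 0.031; 0.52). Cholesterol synthesis genes, cholangiocyte markers and mesothelial markers had 0 called over all genes and 0 adjusted over the list alone. Their medians were 0.69 (0.015; 0.41), 1.26 (0.015; 0.52) and −1.11 (0.024; 0.52).

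The other lists had 0 called over all genes and did not pass. Adjusted over the list alone, contractile genes (median −0.91, camera adjusted p = 0.051) had 1 lower, Acta2 at −3.53 ± 0.68, and Wnt and R-spondin genes (−1.12, 0.051) had 1 higher, Wif1 at 3.98 ± 0.94, and 1 lower. Cytokines and chemokines (−0.63, 0.071) had 2 lower, with Ccl11 at −4.43, retinoid handling genes (0.08, 0.62) had 1 higher, Cyp26a1 at 4.28, and elastic fibre genes (−0.42, 0.36) had 1 higher, Fbn2 at 5.38. None passed adjusted over the list alone in the rest, given as the same pair of values. They are hepatocyte markers (0.86, 0.051), myofibroblast secreted genes (−0.46, 0.11), interferon response genes (−0.44, 0.11), TGF-beta genes (−0.24, 0.13), stellate cell markers (−0.07, 0.62) and cell cycle genes (−0.29, 0.69). Further ones are the PDGF pathway (−0.17, 0.79), epithelial niche ligands (−0.38, 0.69), unfolded protein response genes (0.30, 0.50), and markers of macrophages (−0.37, 0.62, direction up), lymphocytes and neutrophils (1.16, 0.21), smooth muscle and pericytes (−0.14, 0.50) and Schwann cells (−0.56, 0.69). Alas2 was 0.94 (adjusted p = 0.93). Means were −0.06 for retinoid handling genes and −0.03 for macrophage markers (direction up), and 0.20 for the PDGF pathway (direction down). No gene was called after ligation in both cell types. With DESeq2, 112 were higher in both against 13.5 for chance and 26 lower against 1.52 (Fisher's exact test, p = 4.66e-74 and 7.33e-25). Most simulated DESeq2 calls were false, genes are not independent, and hepatocyte RNA in both sorts was not tested.

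The 2 calls became 415 with DESeq2, 11 with edgeR, 4 with the stricter filter, 0 with limma-voom with or without sample weights, without a filter, with 4 CPM added, without uninjured stellate library 1 and ligated Gli1 library 2 together and without any single Gli1 or ligated stellate library, and 21 and 5 without uninjured stellate libraries 1 and 2. List calls were lost by fibrillar collagens (adjusted p = 0.18) and basement membrane genes (0.25) without uninjured stellate library 1, by Hedgehog (0.18) and cholangiocyte genes (0.29) without ligated Gli1 library 1, and by cholesterol synthesis genes (0.14) and mesothelial markers (0.63) without uninjured Gli1 library 2.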

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

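The tests of RNA spread alike, of endothelial RNA of the same make-up, of Gli1 cells in the stellate sort, at the median share and at the share of Dpt, and of a lower share of sorted cells were chosen only after the result was seen. Bounds at the share of Dpt were set with all shares known. The results here stand out because the response to ligation differed between Gli1 and stellate cells by a test of the difference itself. That holds for 2 genes, Plat at −7.12 and Slco2a1 at −6.59, and for lists by the median of Gli1 minus stellate responses as fitted. These medians were −2.65 for portal fibroblast markers, −2.70 for endothelial markers, −1.84 for immediate early genes and −1.62 for complement genes. They were −0.89 for the Hedgehog pathway, −0.57 for fibrillar collagens and collagen processing, −0.58 for basement membrane genes, 0.58 for cholesterol synthesis, 1.14 for cholangiocyte markers and −1.22 for mesothelial markers. All 10 list calls were lost with an estimated correlation (adjusted p = 0.23 to 0.52). With 1 library left out, fibrillar collagens and basement membrane, Hedgehog, cholangiocyte, cholesterol synthesis and mesothelial genes lost theirs (above).

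Cholangiocyte and mesothelial transcripts were abundant in Gli1 libraries, with Krt19 at 1488 and Msln at 1650 CPM before ligation. RNA spread alike over all sorts is argued against, since the median level of 21 markers in stellate libraries was 0.0518% of that in Gli1 libraries before and 0.149% after ligation. One population that carries both sets in fixed proportion is argued against too. In second lists, uninjured Gli1 library 2 over library 1 had a median log2 ratio of 0.82 for mesothelial and −1.71 for cholangiocyte genes, a difference of 2.54 (exact permutation test across 9 and 14 genes, which are not independent, p = 0.00216). Whether other cells entered the sort, or subsets of cells with the reporter express these genes, was not tested and stays open.

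Endothelial markers and the genes Plat and Slco2a1 were higher in ligated stellate libraries. A second endothelial list fixed before its test had a median response of 2.70 there, with 0 of 18 called over all genes and 9 adjusted over the list alone (camera adjusted p = 3e-05; adjusted p = 0.35 with an estimated correlation), so endothelial RNA in that sort may contribute. The second list also rose in Gli1 cells (1.37, camera adjusted p = 0.013; adjusted p = 0.31 with an estimated correlation), and its interaction did not pass (−1.07, camera adjusted p = 0.11). Plat and Slco2a1 had 0.366% and 0.351% of the level in uninjured stellate libraries that the endothelial list would give at a fixed make-up. Endothelial RNA and a response of stellate cells themselves cannot be told apart for these genes, since 2 of 17 endothelial markers, Lyve1 at 3.06% and Vwf at 3.92%, also lay far below that level.

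Portal fibroblast markers responded in opposite directions, with −1.51 in Gli1 cells and 1.21 in stellate cells relative to all genes. At the make-up measured, the rise of Dpt in stellate cells needs a Gli1 cell share of 5.38% and 5.06%. In both libraries 4 of 6 other members of at least 100 CPM lay far below it (5 of 9 at any level). The 4 were Fbln2 (0.306% and 0.92%), Igfbp6 (0.0745% and 0.384%), Mfap4 and Mfap5. That bound was set with the shares known. Far below the median share lay 2 of 10, Mfap4 and Mfap5, where that test needed 3. Gli1 cells and a response of stellate cells thus cannot be told apart. A lower share of sorted mesenchymal cells in the ligated Gli1 libraries stays open. Responses of 6 of 19 members lay over 2 standard errors from the list's median (−4.87 to 0.99). RNA of other cells could give this spread too. A change within Gli1 cells or in which portal cells carried the reporter stays open.

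The other differences are given as values in the report without an explanation: immediate early genes with Egr1 at −3.54, complement genes with C3 at −6.23, Hedgehog genes with Shh at −3.90, fibrillar collagen genes with Loxl2 at −2.72, and basement membrane genes with Lama4 at −3.57.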

How the results depend on the processing

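With 2 libraries in each group, and 4 residual degrees of freedom, the spread behind every p is borrowed across genes and groups, and where a library was left out the lone sample is assumed to vary like the other groups. No called result of a named gene or list changed direction, while some that did not pass did, such as macrophage markers between ligated cell types and smooth muscle and pericyte markers in stellate cells with TMM scaling. Over all settings 3429 called results of named genes kept their call and 847 lost it, and 614 list results kept theirs and 127 lost it. Of 195 called results of named genes, 111 were lost without the 2 libraries with the most RNA of other cells, 76 and 71 without ligated stellate libraries 1 and 2, 74 and 63 without ligated Gli1 libraries 1 and 2, 84 and 60 with limma-voom with and without sample weights, 53 in a fit of the 2 groups compared, 41 with edgeR, 28 without a filter, 21 with the replicate block and 0 with DESeq2. Depth limits what genes under about 10 reads can show.

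Counts are given in the order uninjured cell types, ligated cell types, ligation in Gli1 cells, ligation in stellate cells and interaction, where the values were 1771, 1083, 0, 34 and 2, with 727 genes called between cell types both before and after ligation, 0 called after ligation in both cell types and 57 of 140 list tests. DESeq2 gave 3053, 1687, 422, 1040 and 415, with 1269 and 138 in both, and most calls simulated with few changed genes were false. limma-voom with sample weights gave 327, 1850, 4, 0 and 0, with 290 in both states, and without them 1548, 665, 0, 0 and 0, with 475. A fit of the 2 groups alone gave 353, 1835 and 0 in stellate cells, with 315. edgeR, the planned main test, gave 1190, 624, 0, 61 and 11. RLE and TMM scaling each gave 22 in stellate cells. No filter gave 4 in Gli1 cells, 9 in stellate cells and 0 for the interaction, and the stricter filter 11, 70 and 4, with 2 after ligation in both, where fewer genes were tested. An added value of 4 CPM gave 45, 18 and 0. Camera with an estimated correlation called 0 lists. The replicate block gave 16 calls in stellate cells and 0 for the interaction, and the block within injury state 0 for the interaction. Pairing by replicate number is unknown with so few libraries. Deviations correlated across genes at 0.08 and 0.11 between cell types and −0.05 and 0.00 between states. Groups that share neither gave −0.02 and −0.11. Apart from fewer genes or samples in a setting, the cause was not tested.

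With each library left out, calls ranged from 1002 to 1698 for uninjured cell types, 151 to 1280 for ligated cell types, 0 to 0 in Gli1 cells, 0 to 177 in stellate cells, 0 to 21 for the interaction, 123 to 738 for both states, 0 to 0 after ligation in both cell types and 48 to 62 for lists. The libraries behind the lowest counts were uninjured Gli1 library 1, ligated Gli1 library 1, ligated stellate library 2 and, for both states and lists, ligated Gli1 library 1. Counts in both states moved beyond 1.5 times without either ligated Gli1 library (123 and 265) and either ligated stellate library (146 and 183). Without uninjured stellate library 1 and ligated Gli1 library 2 together, counts were 554, 114, 0, 0 and 0, with 97 in both states and 54 lists. That setting also added 9 list calls, and a single library left out 1 to 11. Macrophage markers passed in stellate cells as up without uninjured stellate library 1 and as down without library 2. They likewise reversed in the uninjured cell types and the interaction. Scaling by library size alone is the deposited CPM and gave no separate value. The block within injury state was not run for the ligation comparisons, since it holds no pair there, nor the fit of 2 groups for the interaction, which needs all 4.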

Other observations

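The test of whether the populations lay closer was fixed before it was run, while the comparison with replicate correlations and the tests of families of genes with a shared name stem, 46 in number, were chosen only after the result was seen, and none of the family tests held with an estimated correlation. The family members named were likewise chosen after the values were seen. S100 genes, calcium-binding proteins, were higher in Gli1 cells for 4 of 12 before ligation (median 1.52 as fitted, camera adjusted p = 7.7e-05; adjusted p = 0.55 with an estimated correlation) and 4 of 12 after (1.48, 7.5e-05; 0.35), beside higher cholangiocyte and mesothelial markers (medians 3.13 and 8.24 before, 5.58 and 6.76 after). The Adamts stem takes in secreted metalloproteases and also Adamtsl genes such as the stellate cell marker Adamtsl2. These genes were lower in ligated Gli1 cells for 5 and higher for 2 of 21 (median −0.94, camera adjusted p = 0.0015; adjusted p = 0.35 with an estimated correlation).

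Cyp, Gst and Ugt genes were higher as families in ligated Gli1 than ligated stellate cells, while Aldh genes, 1 higher and 1 lower of 20, did not pass (median 1.03, camera adjusted p = 0.18). Beside them stood hepatocyte markers, which had 0 of 18 members called and were higher as a list (camera adjusted p = 0.00071; adjusted p = 0.65 with an estimated correlation). That list call was lost without ligated Gli1 library 2 (adjusted p = 0.64), where Alb was 5648 CPM against 990 CPM in library 1. Cyp genes were higher for 7 of 56 (median 1.68, camera adjusted p = 0.00099; adjusted p = 0.55 with an estimated correlation), with Cyp2s1 at 6.27 ± 0.60. Gst genes, which conjugate glutathione, were higher for 4 of 21 (1.52, 0.00099; 0.35), with Gsta3 at 496 ± 79.9 CPM against 36.7 ± 5.71 (3.72 ± 0.60) and Gsta4 at 3.43 ± 0.43. Ugt genes, which conjugate glucuronic acid, were higher for 2 of 12 (2.06, 0.0067; 0.35).

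As a hypothesis, the populations may converge after ligation in genes well above the floor of counting. Over 6068 genes with at least 10 CPM in every library, correlations across genes between Gli1 and stellate libraries were 0.648 to 0.698 before and 0.710 to 0.785 after ligation, so that the lowest ligated value exceeded the highest uninjured one by 0.012. Replicate correlations over these genes were also higher after ligation, at 0.888 and 0.921 against 0.850 and 0.797 in Gli1 and stellate cells. The mean correlation between cell types divided by the geometric mean of the replicate correlations was 0.813 before and 0.813 after ligation. Convergence and lower noise in the ligated libraries thus cannot be told apart, and RNA of other cells that both ligated sorts share stays open too.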
